A study of Mus musculus with 6 samples.

How the data were processed

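Livers of mice on a normal diet (3 samples) and of mice on CDAHFD (3 samples) were profiled by RNA-seq. Per the labels' protocols, total RNA was extracted with TRIzol and 1 µg went into a stranded, ligation-based mRNA library kit, which selects polyadenylated RNA. The submitters' processing notes name STAR 2.7.11a and the genome build GRCm39. The counting tool, the gene annotation, the strand setting and the gene lengths are not given in the sources used here.

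The deposited tables hold 1 row per Ensembl gene for the 6 libraries. The authors deposited raw read counts per gene as whole numbers, and TPM (transcript abundance scaled by gene length and by the library's total), which sum to 1000000 in each library. TPM was 0 exactly where the count was 0, and counts and TPM had Spearman correlations across genes of 0.903 to 0.929 per library. The table's columns were read as CDAHFD where they begin with CD and as normal diet where they begin with ND, with the replicate number of the sample titles, and other per-sample columns not used numbered 0. Total counts per library ran from 21986215 to 25628531, with 19085 to 19454 genes counted at least once on normal diet and 20986 to 21761 on CDAHFD. Alb took 7.72% to 9.69% of counts and the 20 most counted genes 23.3% to 25.6%.

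Of 56847 gene IDs, 51911 matched a symbol in the gene name table. The other 4936 held 0.234% to 0.402% of the counts of a library and kept their ID. The reference at hand is of another build (GRCm38), so no coordinates are given, and it served for names and for the order of neighbouring genes (assembly GRCm38.p6). Some symbols are therefore of an older kind, such as G6pc, Pycrl and Atp5h. Reads shared by near-identical paralogs, or by overlapping genes, are assigned by rules not given here, so single values of such genes are uncertain.

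Genes were kept with edgeR's filterByExpr by group (minimum count 10), which left 14215 of 26131 counted genes. Libraries were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with the diet as its term over all 6 libraries, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are CDAHFD over normal diet, the standard error is the coefficient divided by the root of the test's F, and CPM values use TMM-scaled totals. The biological coefficient of variation was 0.136. The principal component analysis used log2 CPM (prior count 2) of the 1000 most variable genes. No 2 libraries looked like 1 library deposited more than once: within a diet, the chi-square per degree of freedom between libraries was 19.1 to 43.4, against 1 for sampling noise alone.

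Before the data were examined, 50 gene lists with 705 genes were fixed from general knowledge of liver biology, and 649 of these genes were tested. Lists with at least 3 tested members, 46 in all, were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists. The estimated correlation and fry were alternatives. Besides the lists described below, none was tested. A count "adjusted over the list alone" uses the Benjamini-Hochberg adjustment within that list's members. The 13 genes of the list of mitochondrially encoded respiratory genes were not analysed here.

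Genes named in the text follow a rule fixed at the same time. It takes Aldh18a1 and the tested proline list members, and the 10 largest changes in each direction among genes past the threshold with a mean of at least 10 CPM, no overlap between groups and a symbol that is not Gm with a number or of the Rik kind. From each list it takes up to 4 passing members with the largest change and a mean of at least 1 CPM, or the 2 most abundant where fewer than 2 pass, and the first 2 genes written. Some genes that the rule takes are not reported here. Any other gene is said to be chosen after its values were seen.

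The pipeline was tested on simulated data for CDAHFD against normal diet, with 3 libraries per group drawn from the real means for 14215 genes, of which 13945 passed the filter. It recovered 83 of 100 genes changed 2-fold and 32 of 100 changed 1.5-fold, and 10 of 125 calls were false. A list shifted by -0.5 was recovered and 0 of 45 unmoved lists were called. The simulated genes were drawn independently, so this does not measure false calls of lists whose genes vary together, and camera called 14 to 24 lists in the splits of the real libraries that mix the diets. In the simulation a change of 1.5-fold was therefore often missed. Far fewer genes were changed there than the 7404 called in the real comparison, so the adjusted threshold was stricter. The simulated recovery thus does not give the share of real changes that was missed. Counting error adds uncertainty for genes below about 1 CPM.

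The alternatives were other scalings (RLE, total counts, and TMM without the 20 most abundant genes), no filter and a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), a block for the replicate number, and leaving out each library in turn. Scaling to the mean log2 count of the hepatocyte markers was added after the data were seen. It widened the coefficient of variation to 0.162 and, like the fit without a filter, pooled gene variances more strongly than the main fit. Bounds for genes without counts in a group use 3 counts over the group's 3 libraries and cover counting error only. Figures were drawn with matplotlib 3.10.9.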

Results

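Poly(A) RNA from mouse liver was sequenced in 6 libraries, 3 from mice on a normal diet and 3 from mice on CDAHFD, a choline-deficient, amino acid-defined high-fat diet used to induce steatohepatitis in rodents. The deposited counts summed to 21986215 to 25628531 per library. The series title asks what ALDH18A1, the enzyme of the first steps of proline synthesis from glutamate, does in the progression of metabolic dysfunction-associated steatohepatitis. The submitters' design text names lipid metabolism and mitochondrial function as the pathways of interest. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples. All changes are log2 fold changes of CDAHFD over normal diet with their standard errors, n = 3 libraries per diet, and levels are means ± SD of CPM, the counts scaled to a common library size.

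CDAHFD livers carried far more RNA of macrophage, matrix and inflammatory genes and less of many hepatocyte genes. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, went from 0.33 ± 0.0609 to 516 ± 74 CPM, a change of 10.59 ± 0.22. The collagen gene Col1a1 rose by 5.05 ± 0.22, while Scd1, the main hepatic stearoyl-CoA desaturase, fell from 8352 ± 1638 to 542 ± 61.5 CPM (-3.95 ± 0.18). Of 14215 genes tested by edgeR's quasi-likelihood test, 7404 passed an adjusted p of 0.05, with 4057 higher and 3347 lower on CDAHFD. With a change of at least 2-fold the counts were 2609 higher and 509 lower. The groups did not overlap for 60.6% of genes, against 10% by chance. The first principal component held 92.7% of the variance and separated the diets.

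The scaling of the libraries moved the balance of these calls. TMM factors lay between 0.877 and 0.907 on normal diet and 1.09 and 1.14 on CDAHFD. Higher genes made up 54.8% of calls with TMM, 84.5% with total counts alone and 87.8% with the deposited TPM, and the median gene shifted by 0.32 and 0.34 on the log2 scale. Scaling to the hepatocyte markers, an alternative added after seeing the data, shifted it by 0.65 and gave 95.9% of 9562 calls. Alb and Glud1 were among the genes that lost a lower call with total counts, and these, Cpt2, Ndufb5, Ndufs1 and Ttr among those that lost it on log2(TPM + 1). With the hepatocyte markers the calls of the named respiratory chain genes and of Eci1, Etfdh, Acaca, Fasn and Cps1, among others, were lost too. Below, member counts without a scaling named are with TMM, and those with total counts and with the hepatocyte markers stand beside them where the balance of calls moved most. The competitive set test camera called 30 of 46 fixed gene lists, 13 higher and 17 lower. It called 0 with an estimated correlation, where 9 had an unadjusted p under 0.05, while the rotation test fry called 39 in one direction, and camera also called 14 to 24 lists in the 9 other splits of the libraries. Camera compares a list with all other genes, so a list whose median turned above 0 could still be called lower. With the hepatocyte markers, where the median gene lay at 0.67, it called 28 lists.

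Aldh18a1 itself (ENSMUSG00000025007) rose from 0.922 ± 0.253 to 6.8 ± 1.24 CPM, a log2 change of 2.88 ± 0.25 (adjusted p = 3.85e-06), and was higher in each CDAHFD library than in every normal diet library. Its counts were 13, 23 and 20 on normal diet and 153, 167 and 211 on CDAHFD, so it remained a low-abundance transcript. Pycr1, a mitochondrial pyrroline-5-carboxylate reductase that completes proline synthesis, rose by 3.04 ± 0.45 (adjusted p = 0.000189) from 6, 1 and 11 counts in the normal diet libraries, and by 3.80 without normal diet replicate 3. The reductase gene Pycrl did not pass (-0.02 ± 0.14, adjusted p = 0.902). Oat, which links ornithine to the same intermediate, fell by 1.21 ± 0.25 (adjusted p = 0.00188).

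Gls2, the liver-type glutaminase, fell by 1.21 ± 0.14 from 489 ± 51.6 to 212 ± 37.2 CPM. Glud1 fell by 0.55 ± 0.12, and the prolyl hydroxylase gene P4ha1 rose by 0.66 ± 0.17. The rise of Glul (0.31 ± 0.12, adjusted p = 0.0438) no longer passed without any 1 of the 6 libraries, at adjusted p = 0.0688 to 0.193. Prodh2, whose enzyme breaks down hydroxyproline, fell by 0.87 ± 0.13. The proline catabolic genes Prodh (-0.27 ± 0.14, adjusted p = 0.141) and Aldh4a1 (-0.27 ± 0.11, adjusted p = 0.0586) did not pass, nor did P4ha2 (0.29 ± 0.21). Prodh and Aldh4a1 passed as lower without CDAHFD replicate 2, at adjusted p = 0.0304 and 0.0299, and Aldh4a1 without normal diet replicate 3, at 0.0413, but both changed sign with total counts, TPM and the hepatocyte markers. In all, 5 of the 14 tested members of the proline, glutamate and ornithine list rose and 4 fell, and 10 passed when adjusted over the list alone. With TMM the list moved in no common direction, with a median of 0.12 and a mean of 0.32 but a downward camera statistic (adjusted p = 0.946), and its median was -0.05 without normal diet replicate 2. Other scalings moved more members up (total counts 6 higher and 3 lower, hepatocyte markers 10 and 2, medians 0.12 with TMM, 0.45 and 0.79).

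**Figure D1:**
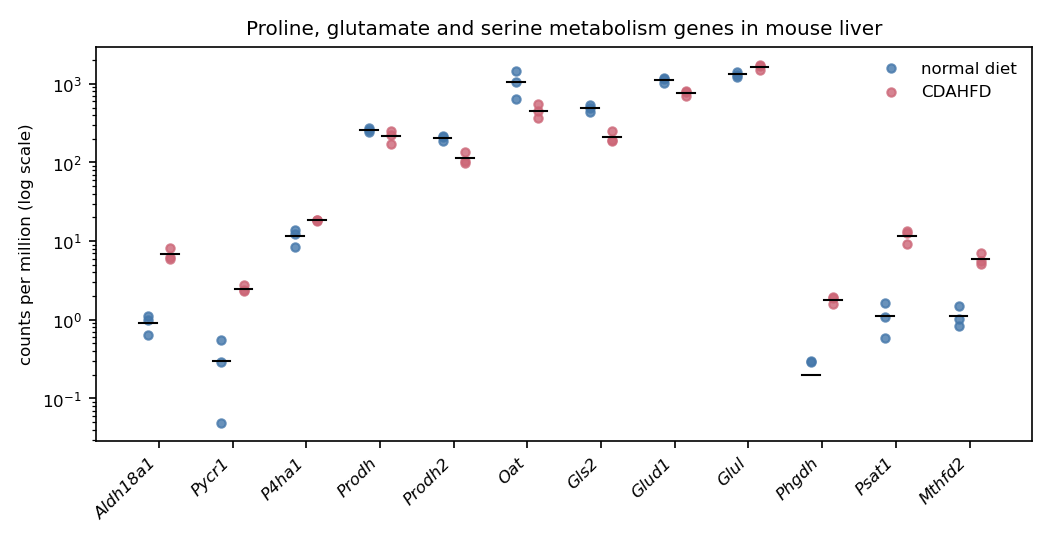
CPM on a log axis for 12 genes of proline, glutamate and serine metabolism in the 6 libraries, with 1 point per library and black lines at the group means. Aldh18a1 points lie between 0.638 and 1.13 CPM on normal diet and between 5.97 and 8.22 CPM on CDAHFD, and the 1 normal diet library without Phgdh counts has no point on the log axis.

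Several serine synthesis genes were higher as well. Phgdh and Psat1, the first 2 enzymes of the pathway from glycolysis to serine, rose, Phgdh by 3.16 ± 0.52 (2.58 without normal diet replicate 2) and Psat1 from 1.11 ± 0.531 to 11.7 ± 2.19 CPM, and the mitochondrial folate enzyme genes Mthfd2 and Mthfd1l rose by 2.40 ± 0.25 and 1.16 ± 0.20. Of 9 tested members of the serine and glycine list 4 rose, 3 fell and 2 did not pass with TMM (8 passed when adjusted over the list alone; total counts 4 higher and 3 lower, hepatocyte markers 6 and 1, medians 0.21 with TMM, 0.53 and 0.87), and camera did not call it (adjusted p = 0.946).

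Most fatty acid synthesis genes fell. Beside Scd1, Thrsp, a lipogenic regulator, fell by 2.66 ± 0.23, the malic enzyme gene Me1 by 2.64 ± 0.22 and the elongase gene Elovl6 by 1.69 ± 0.17. The core synthesis genes fell less, Acaca by 0.86 ± 0.11 and Fasn by 0.82 ± 0.12. Of 15 tested members of the de novo lipogenesis list 12 fell, 1 rose and 2 did not pass, and 14 passed when adjusted over the list alone. Camera gave adjusted p = 3.25e-05 for the list, and adjusted p = 0.206 with an estimated correlation. Cholesterol synthesis genes fell in 13 of 24 cases and rose in 2 with TMM, with 15 passing when adjusted over the list alone (total counts 6 higher and 8 lower, hepatocyte markers 9 and 3). Among them Tm7sf2 fell by 1.79 ± 0.15, Idi1 by 1.16 ± 0.16 and Stard4 by 1.06 ± 0.11. By camera the list had adjusted p = 0.00185, and adjusted p = 0.346 with an estimated correlation. The cholesterol list median was -0.44 with TMM and turned to 0.21 when libraries were scaled to the hepatocyte markers, whose own median was -0.59, while the lipogenesis median went from -0.82 to -0.16 (total counts 2 higher and 9 lower, hepatocyte markers 2 and 5).

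Lipid uptake and droplet genes went both ways. Lpl, the lipase that releases fatty acids from circulating triglyceride, rose by 2.75 ± 0.19 from 27.9 ± 8.62 to 188 ± 17.3 CPM, the fatty acid transporter gene Cd36 by 2.27 ± 0.23, and the droplet coat genes Cidec and Plin4 by 2.51 ± 0.27 and 2.01 ± 0.20. Plin2 did not pass (0.16 ± 0.13). In the lipid droplet and storage list 7 of 20 members rose and 4 fell (11 passed when adjusted over the list alone; total counts 9 higher and 3 lower, hepatocyte markers 14 and 2). Its median was -0.03 with TMM but 0.30 with total counts, 0.33 with TPM, 0.64 when scaled to the hepatocyte markers and 0.07 without normal diet replicate 3, its mean was 0.39, and camera gave adjusted p = 0.831. Apoa4, an apolipoprotein, rose from 17.9 ± 7.27 to 259 ± 89.7 CPM, a change of 3.85 ± 0.33. The lipoprotein assembly gene Mttp fell by 1.05 ± 0.11. In that list 8 of 16 members fell and 2 rose (10 when adjusted over the list alone; total counts 3 higher and 6 lower, hepatocyte markers 7 and 3), and its median of -0.38 turned to 0.0011 with TPM and 0.28 when scaled to the hepatocyte markers. Camera called the lipoprotein list lower (adjusted p = 0.0283), with adjusted p = 0.248 with an estimated correlation and 0.0508 without CDAHFD replicate 2.

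Genes of choline, phosphatidylcholine and methionine metabolism, which the choline-deficient diet bears on directly, fell in 15 of 21 cases and rose in 3 (18 when adjusted over the list alone; total counts 3 higher and 8 lower, hepatocyte markers 6 and 4). Gnmt, the glycine N-methyltransferase that consumes S-adenosylmethionine, fell by 2.00 ± 0.16 and Ahcy by 1.08 ± 0.14. The choline kinase gene Chka rose by 1.04 ± 0.15, and Pemt, which makes phosphatidylcholine by methylation, did not pass (0.05 ± 0.17). The list median was -0.46 with TMM and 0.19 when scaled to the hepatocyte markers. The camera test gave adjusted p = 0.00122, and adjusted p = 0.248 with an estimated correlation.

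Fatty acid oxidation genes were lower on CDAHFD with TMM. In mitochondria Acaa2 fell by 1.04 ± 0.12, Etfdh by 0.95 ± 0.12, Eci1 by 0.87 ± 0.10 and Cpt2 by 0.60 ± 0.10, while Cpt1a, the entry step, did not pass (-0.19 ± 0.11, adjusted p = 0.172). Of the 18 members 14 fell and 0 rose (15 when adjusted over the list alone; total counts 1 higher and 8 lower, hepatocyte markers 3 and 1). The camera result was adjusted p = 7.46e-06, and adjusted p = 0.206 with an estimated correlation. In peroxisomes and omega-oxidation 12 of 14 members fell and 0 rose (12 when adjusted over the list alone), led by Cyp4a10 (-1.82 ± 0.21), Cyp4a14 (-1.41 ± 0.35) and Abcd3 (-1.29 ± 0.12). Other scalings left fewer lower (total counts 0 higher and 9 lower, hepatocyte markers 2 and 4, medians -0.77 with TMM, -0.44 and -0.11). Against all other genes camera gave adjusted p = 1.62e-05, and adjusted p = 0.206 with an estimated correlation. Of 4 ketogenesis genes 3 fell and Bdh1 rose by 0.34 ± 0.12, with all 4 passing when adjusted over the list alone (total counts 1 higher and 1 lower, hepatocyte markers 1 and 0; camera adjusted p = 0.175). Bdh1 no longer passed without normal diet replicates 1 or 2 or CDAHFD replicates 1 or 2, at adjusted p = 0.0728 to 0.207. The median of the mitochondrial oxidation list was -0.59, equal to that of the hepatocyte markers at 2 decimals, and it turned to 0.06 when libraries were scaled to those markers, as the ketogenesis median turned from -0.53 to 0.13.

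Nuclear genes of the respiratory chain fell modestly with TMM. In complex I, Ndufb5 fell by 0.82 ± 0.17, Ndufb9 by 0.81 ± 0.17 and the core subunit gene Ndufs1 by 0.66 ± 0.12, and 20 of 36 members fell with 0 rising (24 when adjusted over the list alone). In complexes II to V, Uqcrb fell by 0.83 ± 0.14, Atp5h by 0.76 ± 0.13 and Sdha by 0.74 ± 0.12, and 26 of 39 fell with 0 rising (26 when adjusted over the list alone). The medians were -0.40 and -0.43 with TMM, -0.07 and -0.11 with total counts, and turned to 0.27 and 0.23 when scaled to the hepatocyte markers. With total counts 5 members of complex I were called lower and 1 higher, and 8 and 0 of complexes II to V. With the hepatocyte markers 0 were lower, and 8 and 10 were higher. Camera with TMM gave adjusted p = 3.13e-05 for complex I and 6.23e-06 for complexes II to V, and adjusted p = 0.346 and 0.374 with an estimated correlation. With the hepatocyte markers the median of all tested genes was 0.67. Camera at the preset correlation still called both lists lower than other genes there (adjusted p = 0.00284 and 0.000251). The 13 genes encoded in mitochondrial DNA were not analysed here.

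Other mitochondrial lists moved the same way with TMM. Pdhb of the pyruvate dehydrogenase complex fell by 0.95 ± 0.10 and Sucla2 by 0.93 ± 0.14, whereas Idh2 rose by 0.75 ± 0.10. Of 17 tricarboxylic acid cycle genes 9 fell and 1 rose with TMM (10 when adjusted over the list alone; total counts 6 higher and 4 lower, hepatocyte markers 9 and 0), with a median of -0.28 that turned to 0.05 with total counts, 0.09 with TPM and 0.37 when scaled to the hepatocyte markers. Tested by camera, the list had adjusted p = 0.0153, and adjusted p = 0.346 with an estimated correlation. Among 24 genes of mitochondrial biogenesis, dynamics and quality control 15 fell and 0 rose with TMM (15 when adjusted over the list alone; total counts 2 higher and 4 lower, hepatocyte markers 7 and 0). They included Tfam, which maintains mitochondrial DNA, at -0.84 ± 0.11, the fusion gene Opa1 at -0.77 ± 0.12 and the chaperonin gene Hspd1 at -0.81 ± 0.14, while Ppargc1a did not pass (0.16 ± 0.22). That list had a median of -0.39, which was -0.07 with total counts and turned to 0.26 when scaled to the hepatocyte markers. For this list camera gave adjusted p = 0.000222, and adjusted p = 0.24 with an estimated correlation.

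**Figure D2:**
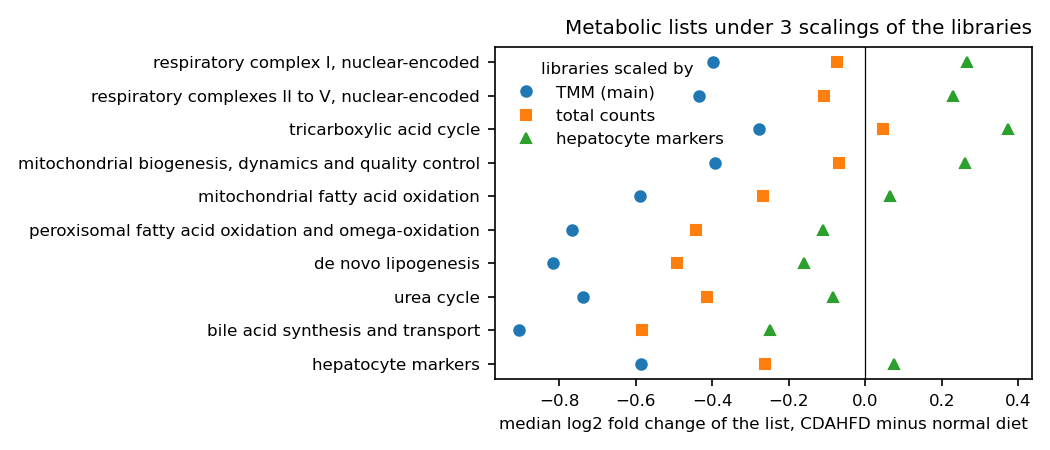
Median log2 fold change, CDAHFD over normal diet, of 10 metabolic gene lists with libraries scaled by TMM, by total counts and to the hepatocyte markers. The 2 respiratory chain lists lie at -0.40 and -0.43 with TMM and at 0.27 and 0.23 with the hepatocyte markers, while bile acid genes lie below 0 with all 3 scalings (-0.25 with the markers).

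Hepatocyte functions were lower in several lists with TMM. Bile acid genes fell in 16 of 19 cases and rose in 1 (18 when adjusted over the list alone), where Cyp7b1 fell by 2.87 ± 0.28, the transporter genes Slco1a1 and Slc10a1 by 2.34 ± 0.20 and 1.86 ± 0.15, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 118 ± 34 to 39 ± 25.6 CPM (adjusted p = 0.00506). Fewer were lower with other scalings (total counts 2 higher and 13 lower, hepatocyte markers 2 and 7, medians -0.91 with TMM, -0.58 and -0.25). Without CDAHFD replicate 2 Cyp7a1 fell by 2.26. By camera the list had adjusted p = 6.23e-06, and adjusted p = 0.206 with an estimated correlation. Of 8 urea cycle genes 7 fell (7 when adjusted over the list alone), among them Otc by 1.19 ± 0.15, Asl by 1.12 ± 0.16 and Cps1 by 0.77 ± 0.14. Scalings again differed (total counts 0 higher and 6 lower, hepatocyte markers 1 and 3, medians -0.74 with TMM, -0.41 and -0.08). The camera test gave adjusted p = 0.00084, and adjusted p = 0.346 with an estimated correlation. Among 16 xenobiotic cytochromes P450 and their regulators 14 fell and 0 rose (15 when adjusted over the list alone), with Cyp2c29 at -5.22 ± 0.20 and Cyp2c54 at -3.30 ± 0.28. The camera result was adjusted p = 3.24e-06, and adjusted p = 0.279 with an estimated correlation. For the P450 list, too, scalings differed (total counts 0 higher and 8 lower, hepatocyte markers 1 and 7, medians -0.66 with TMM, -0.34 and -0.01). The Cyp2c genes are close paralogs whose reads the authors' counting may have split, so single values are uncertain. Glucose metabolism genes split with TMM, 8 of 17 rising and 7 falling (15 when adjusted over the list alone, camera adjusted p = 0.703), and less evenly otherwise (total counts 10 higher and 6 lower, hepatocyte markers 10 and 3, medians 0.23 with TMM, 0.56 and 0.89). The gluconeogenic genes G6pc and Pck1 fell by 2.30 ± 0.19 and 1.03 ± 0.17, and the glycolytic genes Hk3, Pkm and Pfkp rose by 2.98 ± 0.20, 2.82 ± 0.12 and 2.18 ± 0.15.

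Hepatocyte identity markers fell in 8 of 11 cases and rose in 0 (9 when adjusted over the list alone), including Tat at -1.36 ± 0.19, Ttr at -0.67 ± 0.15 and Alb, the most counted gene in each library, at -0.47 ± 0.15 (adjusted p = 0.0236). Alb alone of these did not pass without CDAHFD replicate 1, CDAHFD replicate 3 or normal diet replicate 1, at adjusted p = 0.0647 to 0.087. Their median of -0.59 was -0.26 with total counts and turned to 0.07 under the scaling built from them (total counts 1 higher and 5 lower, hepatocyte markers 3 and 2). Against all other genes camera gave adjusted p = 0.00114, and adjusted p = 0.346 with an estimated correlation. Periportal markers fell in 8 of 10 cases, among them Cyp2f2 at -1.51 ± 0.15, and 1, Cdh1, rose by 1.28 ± 0.29 (9 when adjusted over the list alone). Tested by camera, the list had adjusted p = 0.00341, and adjusted p = 0.346 with an estimated correlation. By scaling, the periportal calls were as follows: total counts 2 higher and 7 lower, hepatocyte markers 2 and 5, medians -0.85 with TMM, -0.53 and -0.20. Pericentral markers split with TMM, with 5 of 12 rising and 6 falling (11 when adjusted over the list alone; total counts 5 higher and 2 lower, hepatocyte markers 5 and 2), among them Slc13a3 at 2.56 ± 0.14 and Oat at -1.21 ± 0.25. Their median was -0.38 with TMM and 0.27 when scaled to the hepatocyte markers, their mean was 0.02, and camera did not call them (adjusted p = 0.403).

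Genes with higher expression in male than in female liver were among the most reduced. Serpina1e fell by 5.02 ± 0.63, Hsd3b5 by 4.33 ± 0.56, Cyp4a12a by 3.04 ± 0.22 and Mup3 by 2.65 ± 0.20. Of 14 members 13 fell, and the remaining one, Mup20, did not pass (0.37 ± 0.18) but was called higher with total counts, TPM, the hepatocyte markers and no filter, at adjusted p = 0.00357, 0.0131, 1.49e-07 and 0.0129, and without CDAHFD replicate 1, at 0.0419. All 13 passed when adjusted over the list alone, the median was -2.65, and camera gave adjusted p = 5.49e-07, with adjusted p = 0.259 with an estimated correlation. CDAHFD replicate 2 kept more of several of these transcripts than the other CDAHFD libraries, 803 CPM of Serpina1e against 146 and 159, and without it Serpina1e was at -6.33 and Hsd3b5 at -5.48. Of 5 tested female-biased genes 3 rose, with Cyp2b9 at 3.71 ± 0.61 (5.55 without normal diet replicate 2), and 1 fell (4 when adjusted over the list alone, camera adjusted p = 0.335). The Mup, Serpina1 and Cyp4a members belong to families of near-identical copies, so their single values are uncertain.

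Matrix and stellate cell genes rose. Timp1, an inhibitor of matrix metalloproteinases, rose by 6.69 ± 0.40 (8.23 without normal diet replicate 1), with Col3a1 at 3.87 ± 0.20 and Col1a2 at 3.76 ± 0.20. Of 25 extracellular matrix and collagen processing genes 24 rose and 0 fell (24 when adjusted over the list alone). Camera gave adjusted p = 9.76e-13, and adjusted p = 0.206 with an estimated correlation. Stellate cell markers rose in 10 of 12 cases and fell in 1 (11 passed when adjusted over the list alone). Those that rose included Pdgfrb at 2.39 ± 0.15, Cygb at 2.34 ± 0.18 and the myofibroblast gene Acta2 at 2.20 ± 0.32. Reln, expressed by stellate cells, was at 0.89 ± 0.11. By camera the list had adjusted p = 0.00185, and adjusted p = 0.346 with an estimated correlation.

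**Figure D3:**
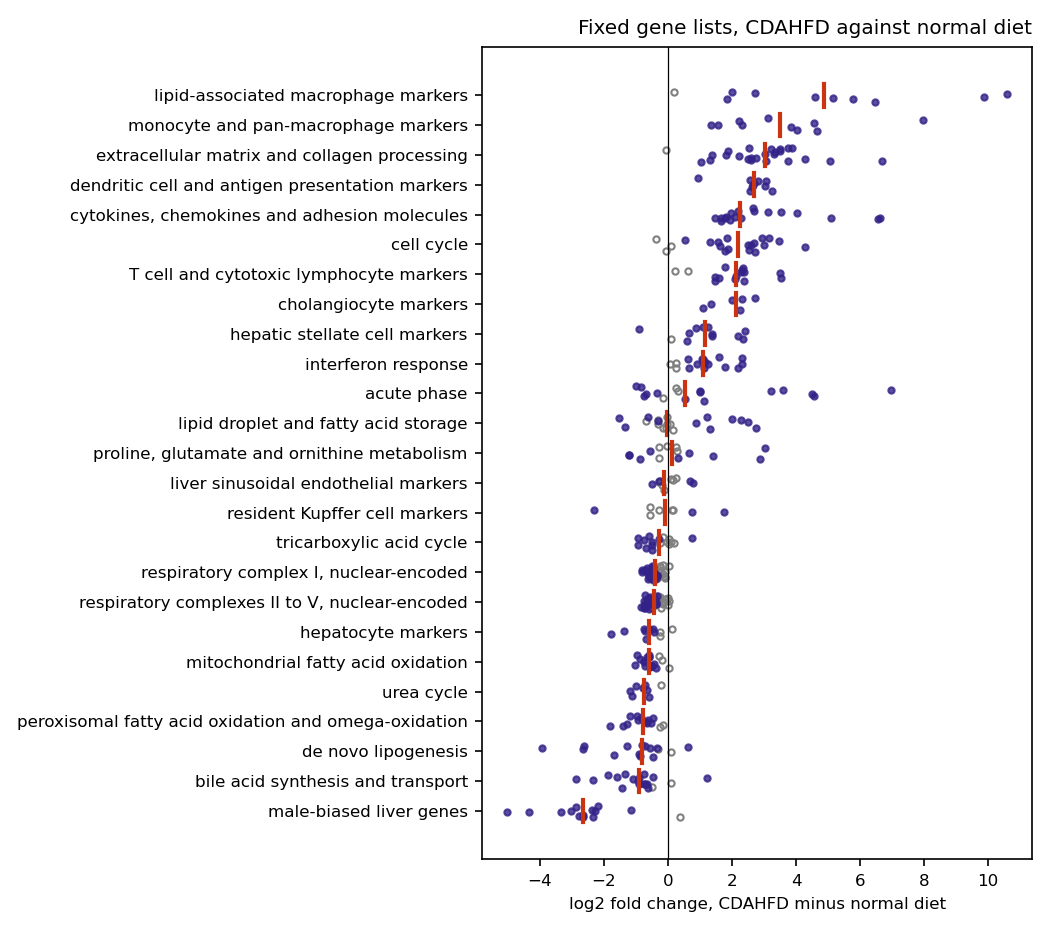
Log2 fold change, CDAHFD over normal diet, of each tested member of 25 fixed gene lists, filled where the gene passed an adjusted p of 0.05 and open where it did not, with red bars at the list medians. Medians run from 4.87 for lipid-associated macrophage markers to -2.65 for male-biased liver genes, and the respiratory chain medians of -0.40 and -0.43 with TMM turn above 0 with the hepatocyte-marker scaling.

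Lipid-associated macrophage markers had the highest median of the cell type lists, at 4.87. These genes rose in 9 of 10 cases (9 when adjusted over the list alone), with Mmp12 at 9.88 ± 0.22, Trem2 at 6.47 ± 0.22, Itgax at 5.79 ± 0.18 and Spp1 at 2.72 ± 0.13. The camera test gave adjusted p = 5.45e-07, and adjusted p = 0.206 with an estimated correlation. All 10 monocyte and pan-macrophage markers rose, also when adjusted over the list alone, with Ccr2 at 4.04 ± 0.20 and Cx3cr1 at 4.66 ± 0.23. The camera result was adjusted p = 9.76e-07, and adjusted p = 0.206 with an estimated correlation. Resident Kupffer cell markers were not called as a set. Among 8 members Marco rose by 1.74 ± 0.53, 1 more rose and Cd163 fell by 2.30 ± 0.53, while Clec4f did not pass (-0.29 ± 0.19). In that list 3 passed when adjusted over the list alone (total counts 4 higher and 1 lower, hepatocyte markers 4 and 1), with camera adjusted p = 0.668. These values depended on CDAHFD replicate 2. Without it Marco was at 0.61 (adjusted p = 0.0922), Cd163 at -3.73 and Clec4f passed as lower (adjusted p = 0.00499), and without normal diet replicate 1 Marco had adjusted p = 0.0644. DESeq2 and limma-voom did not call Marco either, at adjusted p = 0.0569 and 0.0525. The Kupffer median of -0.08 with TMM turned to 0.23 with total counts, 0.24 with TPM, 0.55 when scaled to the hepatocyte markers and 0.01 without CDAHFD replicate 3.

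Several other leukocyte lists rose as well. T cell and cytotoxic genes rose in 13 of 15 cases (13 when adjusted over the list alone), with Cd8a at 3.50 ± 0.47 and Cd3e at 2.27 ± 0.35. Against all other genes camera gave adjusted p = 6.04e-05, and adjusted p = 0.248 with an estimated correlation. All 10 dendritic cell and antigen presentation genes rose, also when adjusted over the list alone, among them H2-Eb1 at 3.02 ± 0.19. All 4 tested neutrophil markers did too (4 when adjusted over the list alone), with S100a9 at 4.40 ± 0.43. Camera gave adjusted p = 3.24e-06 and 0.00149 for these 2 lists, and adjusted p = 0.206 for both with an estimated correlation. Of 8 B and plasma cell markers 4 rose, including Igkc at 1.52 ± 0.20, and 1 fell (5 when adjusted over the list alone, camera adjusted p = 0.21).

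Among the other cell types, all 6 cholangiocyte markers rose (6 when adjusted over the list alone), with Krt19 at 2.31 ± 0.39 and Epcam at 2.25 ± 0.28. Tested by camera, the list had adjusted p = 0.00433, and adjusted p = 0.245 with an estimated correlation. Sinusoidal endothelial genes were not called as a set, with 2 of 11 rising, among them Lyve1 at 0.80 ± 0.20, 2 falling and Stab2 at 0.10 ± 0.10 (3 when adjusted over the list alone; total counts 5 higher and 0 lower, hepatocyte markers 9 and 0). Their median was -0.12 with TMM, 0.20 with total counts, 0.24 with TPM and 0.53 when scaled to the hepatocyte markers, their mean was 0.03, and camera gave adjusted p = 0.639. Of 3 mesothelial markers 2 rose (2 when adjusted over the list alone, camera adjusted p = 0.491), with a median of 0.91 that was -0.97 without a filter on low counts. That median was also below 0 without CDAHFD replicate 1 (-0.17), CDAHFD replicate 3 (-0.36) or normal diet replicate 3 (-0.23). Of 6 erythroid markers 1, Alas2, fell by 0.86 ± 0.12 (1 when adjusted over the list alone, camera adjusted p = 0.633, median 0.05 and mean -0.05; total counts 0 higher and 1 lower, hepatocyte markers 4 and 0), and the median was -0.27 without CDAHFD replicate 3 and -0.23 without normal diet replicate 1. The exocrine pancreas, adipocyte and skeletal muscle lists had 1 tested gene each, of which Cd36 alone passed, in the adipocyte list.

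Inflammatory genes rose. All 18 tested cytokine, chemokine and adhesion genes rose, also when adjusted over the list alone, with the monocyte chemoattractant gene Ccl2 at 5.10 ± 0.42 (6.44 without normal diet replicate 1). For this list camera gave adjusted p = 8.66e-08, and adjusted p = 0.206 with an estimated correlation. Interferon response genes rose in 14 of 17 cases (14 when adjusted over the list alone), with Oasl2 at 2.31 ± 0.18 and Gbp2 at 2.20 ± 0.21. By camera the list had adjusted p = 8.74e-05, and adjusted p = 0.346 with an estimated correlation. The acute phase list divided, with 9 of 17 higher and 5 lower with TMM (14 when adjusted over the list alone, camera adjusted p = 0.11; total counts 11 higher and 3 lower, hepatocyte markers 12 and 0, medians 0.53 with TMM, 0.85 and 1.18). Lcn2 went from 3.23 ± 0.842 to 407 ± 72.5 CPM, Orm2 and Saa2 rose by 4.56 ± 0.21 and 4.51 ± 0.44, and the fibrinogen gene Fga fell by 0.74 ± 0.15.

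Cell cycle genes rose from low levels in 17 of 20 cases (17 when adjusted over the list alone), with Plk1 at 3.48 ± 0.31, Ccnb1 at 3.16 ± 0.30 and the proliferation marker Mki67 at 2.51 ± 0.21. The camera test gave adjusted p = 1.5e-06, and adjusted p = 0.206 with an estimated correlation. Cdkn1a, which encodes the p21 cell cycle inhibitor, rose by 2.98 ± 0.21, and 8 of 10 p53 target and senescence genes rose and 1 fell (9 when adjusted over the list alone). Of 7 oncofetal liver genes 6 rose (6 when adjusted over the list alone), with Ly6d at 6.45 ± 0.40, H19 at 4.40 ± 0.42 and alpha-fetoprotein, Afp, at 1.30 ± 0.23. Camera gave adjusted p = 0.00396 for the p53 list and 0.00253 for the oncofetal list, and adjusted p = 0.206 for both with an estimated correlation.

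Stress genes were mixed. Atf3 rose by 5.38 ± 0.26 and Asns, the asparagine synthetase gene, by 2.27 ± 0.32 (2.90 without normal diet replicate 1), while Herpud1 and the endoplasmic reticulum chaperone gene Hspa5 fell by 1.39 ± 0.13 and 0.69 ± 0.12, and Ddit3 did not pass (0.21 ± 0.23). In the unfolded protein and integrated stress list 5 of 19 rose and 8 fell with TMM (15 when adjusted over the list alone, camera adjusted p = 0.303; total counts 7 higher and 6 lower, hepatocyte markers 9 and 2). Its median was -0.24 with TMM but 0.07 with total counts, 0.06 with TPM and 0.40 when scaled to the hepatocyte markers, and its mean was 0.20. In oxidative stress defence 7 of 17 rose, among them Gsta1 at 3.47 ± 0.32 and Hmox1 at 2.07 ± 0.11, and 3 fell with TMM (10 when adjusted over the list alone, camera adjusted p = 0.321; total counts 9 higher and 2 lower, hepatocyte markers 14 and 1, medians 0.41 with TMM, 0.74 and 1.08). Of 14 circadian clock genes 7 fell and 0 rose with TMM (7 when adjusted over the list alone; total counts 1 higher and 3 lower, hepatocyte markers 6 and 0), with Ciart at -0.97 ± 0.16 and Hlf at -0.95 ± 0.13. Their median of -0.31 turned to 0.02 with total counts, 0.05 with TPM and 0.36 when scaled to the hepatocyte markers. The camera result was adjusted p = 0.0236, with adjusted p = 0.346 with an estimated correlation and 0.0642 without normal diet replicate 1. Immediate early genes, which respond to tissue handling within minutes, rose in 6 of 10 cases, including Fos at 2.75 ± 0.24, and fell in 1 (8 when adjusted over the list alone, camera adjusted p = 0.0717, or 0.00771 without normal diet replicate 1).

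Under the naming rule for the largest changes, which asks for a mean of at least 10 CPM, the largest rises were those of Gpnmb, Mmp12 and Lcn2. Of the genes not named above, the 10 largest changes in each direction held on the higher side Adam8 (6.57 ± 0.21), Ubd (5.77 ± 0.22) and Smpd3 (5.37 ± 0.19). On the lower side they held Mup15 (-5.92 ± 0.86), Serpina4-ps1 (-5.10 ± 0.61), Mup17 (-4.71 ± 0.77), Mup7 (-4.40 ± 0.57), the carboxylesterase gene Ces2a (-3.76 ± 0.17) and AC127342.1 (-3.72 ± 0.35). Without CDAHFD replicate 2 the changes of Mup7, Serpina4-ps1 and AC127342.1 were -5.58, -6.56 and -4.55, and those of Mup15 and Mup17 were -6.76 and -5.38. Without normal diet replicate 3 Mup15 and Mup17 were at -4.28 and -3.55. The Mup values and that of Serpina4-ps1, a pseudogene, are uncertain for the reason of shared reads given above.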

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

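Aldh18a1 kept its direction and stayed past the threshold under each alternative run, with log2 changes of 2.00 to 3.53. The lowest came on the log2(TPM + 1) scale, which understates changes of low genes, and leaving out 1 library gave 2.66 to 3.04. Genes past the threshold numbered 6531 to 7520 with 1 library left out and 6747 to 8009 under the other alternatives chosen before the data were seen, and DESeq2 gave 7230. Scaling to the hepatocyte markers, chosen after seeing the data, gave 9562 genes, and 4870 with a 2-fold change against 3118. The prior degrees of freedom, by which edgeR pulls the spread of single genes to the trend, were 7.35 in the main test and 35.9 with those markers, and without a filter (8009 genes) they had no upper bound. Without that bound a gene's own spread does not enter the test, and Marco had adjusted p = 4.37e-27 without a filter against 0.0165, at a change of 1.74 in both fits. How far the prior moved the counts of genes was not tested. Calls with total counts shared 5204 genes with those of TMM. These scalings move all genes by a near-constant amount, which is what turns the signs of small changes. Over the alternatives, 29 values of named genes and 45 list medians changed sign, while 2546 gene values and 688 list results kept both direction and side of the threshold. The estimated correlation and fry entered this list tally only for lipogenesis, mitochondrial oxidation, complex I and complexes II to V. The tally therefore leaves out most of the calls lost with the estimated correlation, which called 0 lists against 30. DESeq2 was not run for the lists.

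With total counts the log2 changes that turned were Aldh4a1 0.053, Clec4f 0.023, Cpt1a 0.13, Prodh 0.056 and Pycrl 0.30, and the list medians lipid droplet 0.30, tricarboxylic acid cycle 0.045, stress response 0.075, clock 0.021, Kupffer 0.23 and endothelial 0.20. On log2(TPM + 1) these were Aldh4a1 0.093, Clec4f 0.030, Cpt1a 0.17, Prodh 0.081 and Pycrl 0.36, with medians lipid droplet 0.33, lipoprotein 0.0011, tricarboxylic acid cycle 0.091, stress response 0.057, clock 0.048, Kupffer 0.24 and endothelial 0.24. On log2(TPM + 0.1) they were Aldh4a1 0.094, Clec4f 0.030, Cpt1a 0.17, Prodh 0.082 and Pycrl 0.36, with medians lipid droplet 0.33, lipoprotein 0.0012, tricarboxylic acid cycle 0.092, stress response 0.058, clock 0.048, Kupffer 0.25 and endothelial 0.24. With the hepatocyte markers they were Alb 0.19, Aldh4a1 0.38, Clec4f 0.34, Cpt1a 0.46, Cpt2 0.050, Glud1 0.10, Igfals 0.16, Prodh 0.38 and Pycrl 0.65, with medians cholesterol 0.21, lipid droplet 0.64, mitochondrial oxidation 0.064, ketogenesis 0.13, lipoprotein 0.28, choline 0.19, complex I 0.27, complexes II to V 0.23, tricarboxylic acid cycle 0.37, mitochondrial biogenesis 0.26, stress response 0.40, clock 0.36, hepatocyte 0.074, pericentral 0.27, Kupffer 0.55 and endothelial 0.53. Without a filter on low counts the mesothelial median was -0.97. With 1 library left out, the values whose sign turned ranged over Pemt -0.16 to 0.17, Ppargc1a -0.11 to 0.34, Pycrl -0.19 to 0.074, erythroid -0.27 to 0.33, lipid droplet -0.094 to 0.074, mesothelial -0.36 to 0.90, proline -0.046 to 0.12 and Kupffer -0.35 to 0.010, and the cause was not tested.

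The lists past the threshold numbered 28 to 31 under other scalings, filters, TPM and voom, but 0 with an estimated correlation, where lipogenesis and mitochondrial oxidation had adjusted p = 0.206, complex I 0.346 and complexes II to V 0.374. The fry test called 39. The replicate numbers showed no clear pairing of the samples. The deviations of same-numbered libraries had correlations of -0.047, 0.069 and 0.118 across genes, and other pairs -0.145 to 0.089. So few libraries cannot exclude a pairing. With the replicate block 7357 genes passed, 3126 with a 2-fold change, and 30 lists, with Aldh18a1 at 2.88 and medians of -0.82, -0.60, -0.38 and -0.43 for lipogenesis, mitochondrial oxidation, complex I and complexes II to V. Depth limits the genes below about 1 CPM on normal diet, such as Aldh18a1 and Pycr1, whose fold changes carry the counting error of few reads.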

Other observations

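Gene families formed from shared symbol stems, a grouping made after the main results were seen, added other themes. Of 15 tested matrix metalloproteinase (Mmp) genes 14 rose and 1 fell, and of 13 Adamts proteases 12 rose. Among 15 tumour necrosis factor receptor (Tnfrsf) genes 14 rose, among 10 annexin (Anxa) genes 8, among 12 Toll-like receptor (Tlr) genes 11, among 17 Ifi genes 14 and among 20 immunoglobulin kappa variable (Igkv) genes 13. On the lower side 46 of 69 cytochrome P450 (Cyp) genes fell and 11 rose, 15 of 18 major urinary protein (Mup) genes fell, and 13 of 17 UDP-glucuronosyltransferase (Ugt) genes fell. The peroxin (Pex) genes, which build peroxisomes, fell in 13 of 16 cases with a median of -0.44, which turned to 0.22 when scaled to the hepatocyte markers. The Psmd genes, 1 family of proteasome genes, fell in 11 of 14 with a median of -0.37, which was 0.0055 with TPM and 0.29 with those markers. The medians of the other families named so far kept their sign under each scaling. Camera called 38 of 149 families, 20 higher and 18 lower, and 0 with an estimated correlation (9 at an unadjusted p under 0.05), where the families named so far had adjusted p = 0.446 except Tlr with 0.47. More of the families called lower had medians that turned, such as Hsd (-0.644 with TMM, 0.00236 with the hepatocyte markers), Ces (-0.577 and 0.0822) and Mrpl (-0.144, and 0.182 with total counts). The Psmb family of proteasome genes was not called, with 3 of 10 higher, 3 lower and a median of -0.156.

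Some genes were counted on CDAHFD alone, and those named here were chosen after their values were seen. Vmn2r3, annotated as a vomeronasal receptor, had 0 counts in the normal diet libraries and 668, 154 and 360 on CDAHFD, at least 306-fold higher, while its neighbours Vmn2r2 and Vmn2r4 had 0 counts in all 6 libraries. Vsig8 was at least 108-fold higher, the translation factor gene Eef1a2 37.8-fold and Pdcd1, the immune checkpoint receptor PD-1, 26.4-fold at the least. Of the list members only Chil3, a monocyte and pan-macrophage marker, was without counts in a group, and that list's median stayed at 3.49 with Chil3 at its bound.

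Of the tests below, those of growth hormone genes, tRNA synthetases and the list counts over splits were fixed before their results were seen, and the others were chosen after. The real split gave 7404 genes, 3118 with a 2-fold change, and 30 lists, each more than in any other split (1 of 10 splits gave as many). The highest of the other splits gave 0 genes, 0 genes with a 2-fold change and 24 lists. With 10 splits no share can fall below 0.05. Each of the other splits mixes the diets, so the diet difference enters the spread within its groups and holds down its gene calls. Their gene counts therefore do not measure what chance alone would give. At an unadjusted edgeR p under 0.05 the other splits gave 48 to 182 genes and the real one 8200.

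Nuclear respiratory genes and mitochondrial oxidation genes were lower with TMM in the same libraries in which macrophage and stellate markers were higher. Part of this may reflect more RNA from other cell types: relative to the hepatocyte markers, the 75 respiratory genes differed by 0.251 and the oxidation genes by 0.0731 (mean log2 CPM), so neither fell more than the markers. The choice of scaling also bears on it, since 8 of the 39 genes of complexes II to V were called lower with total counts against 26 with TMM. The means of the lipogenic and bile acid lists went beyond that, at -0.438 and -0.331 relative to the markers, by more than 2 pooled SDs of the libraries. Not all members shared in this. With libraries scaled to the markers, 5 of 15 lipogenic genes were called lower and 2 higher, and 7 of 19 bile acid genes lower and 2 higher. For the genes still called lower this argues against a lower hepatocyte share as the whole cause. It does not for the others, such as Fasn and Acaca. For the respiratory and oxidation genes a fall within hepatocytes stays open.

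The male-biased genes fell far more than the hepatocyte markers, by -2.05 relative to them, which argues against a changed cell makeup as the cause. Female libraries were not the cause either, since the CDAHFD library with the lowest summed CPM of 4 Y-linked genes kept 0.537 of the normal diet mean and Xist had 0 to 6 counts in each library. The fall was not confined to families with shared reads: Elovl3, Cyp7b1, Susd4 and Cyp2u1, members outside the large families, had a median of -2.47 and were all called lower. They were picked after the calls of the list were seen, so they are no separate test. For the Mup, Serpina1 and Cyp4a members the part of shared reads was not tested. Growth hormone signalling, which maintains the male pattern, stays open as a candidate explanation: Igf1 (-0.80 ± 0.15) and Igfals (-0.49 ± 0.12) fell with TMM, Igfals was not called with total counts or TPM, and neither was called with the hepatocyte markers, but Socs2 (1.47 ± 0.27) and Cish (from 5.55 ± 3.72 to 15.7 ± 2.52 CPM) rose. Their median was 0.49, above the bound set in advance, so by that rule weaker growth hormone signalling was not the cause. The bound may be the wrong measure, because inflammatory cytokines also induce the latter pair, but that was not tested here. With genes going both ways the question stays undecided.

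Aldh18a1, Pycr1 and the serine synthesis genes Phgdh and Psat1 rose together, as did Asns and Mthfd2, all known targets of the amino acid stress factor ATF4. A response of that kind stays open. The unfolded protein and integrated stress list was mixed, with 5 of 19 members higher and 8 lower with TMM (total counts 7 and 6, hepatocyte markers 9 and 2). Atf3 and Asns rose there, but Ddit3 did not pass (0.21 ± 0.23). The median over 20 cytosolic aminoacyl-tRNA synthetase genes, not all of which need be ATF4 targets, was -0.187 with TMM (3 higher and 6 lower). It was -0.205 with RLE, 0.138 with total counts and 0.172 and 0.177 with TPM, all under the bound set in advance, and 0.471 with the hepatocyte markers, above it but below the value set for such a response. The bound took no account of a changed cell makeup. That last scaling, added after seeing the data, allows for it only if the marker genes are unchanged within hepatocytes, which was not tested. Of the 11 markers, 3 were called higher and 2 lower under it. The rise of Aldh18a1 and the genes named with it could also come from cells other than hepatocytes arriving in the tissue, as the monocyte and pan-macrophage markers had a median of 3.49. In bulk tissue these cannot be told apart, because no value here gives the cell of origin of Aldh18a1 RNA.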
